A study of Mus musculus with 6 samples.

How the data were processed

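The study profiled heart RNA of wild-type ICR mice, an outbred stock, at day 4, with 3 samples from the offspring of mothers injected with citric acid (control) and 3 from the offspring of mothers injected with STZ, read here as streptozotocin. Per the labels' protocols, total RNA was purified on silica columns and libraries were made with a SMARTER mRNA-seq kit. Per the submitters' processing notes the genome build was GRCm38 (mm10). The aligner, the counting program and the strand setting are not given in the sources used here. Groups and replicate numbers were read from the sample titles and treatment labels, and 1 table holds all 6 samples and 54532 genes.

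The deposited values are FPKM-type values, per kilobase of the gene length given in the same table and per a scale that the authors set for each sample. No header states this: it was read from the abbreviation the authors gave the table and from the values themselves. Whether fragments or reads were counted is not given, and FPKM is used throughout as the name of the unit. Each value multiplied by the deposited gene length was a whole multiple of 1 step per sample: 100% of the values above 0 came out whole within 0.01 reads. The recovered totals were 17085434, 17732294 and 17307818 reads for controls 1 to 3 and 17567807, 16707268 and 18082599 reads for STZ 1 to 3. The authors' scale was 0.985 to 1.03 times these totals in 5 libraries and 1.21 times in control 2. Because the unit is FPKM, count models were not the main test. Reads of genes with near-identical copies may have been split or dropped by counting that is not described, and reads of overlapping or antisense genes cannot be told apart without a stated strand setting.

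The main test was limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(FPKM + 1), for 12431 genes at 1 FPKM or more in at least 3 samples, with group as the only term. P-values were two-sided and Benjamini-Hochberg (BH) adjusted over all genes tested, with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates those of low genes. Genes fixed in advance also had an exact permutation test over the 20 assignments of 3 of 6 samples, whose smallest two-sided p is 0.1. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, BH-adjusted over the 41 of 49 lists with at least 4 tested members, and again with an estimated correlation and with fry. The estimated correlation ran from -0.057 for fetal sarcomere genes to 0.946 for the tricarboxylic acid cycle, and was 0.636 for matrix genes. The lists, cell type markers, tests, alternatives and naming rule were fixed before the data were examined.

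The rule named 13 genes from the series title and textbook heart biology whatever their values. It added genes past the threshold with a mean of at least 5 FPKM in the higher group, non-overlapping groups and a symbol that is not a predicted, clone, microRNA, snoRNA or pseudogene name, up to 10 per direction. Where none qualified, the 5 with the lowest unadjusted p in a direction that met the other criteria were named as not past the threshold, and 1 of the lower ones is not reported here. For each list with a member at an unadjusted p under 0.05, the 2 members with the lowest p are part of the rule, of which the closing section gives those not in the report. Xist and Y-linked genes served as a check of sex.

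The fit was tested on simulated counts for the same 12431 genes and 3 against 3 samples, with 200 genes changed, drawn from those above a low limit of reads. With the spread of all 6 libraries, 47.0% of genes changed 2-fold and 85.0% of genes changed 4-fold were recovered, with 6 and 9 false calls. With the spread of the 5 libraries other than control 2, the shares were 70.5% and 96.5%. Alternatives covered the pseudocount, the filter on low values, the scaling, a replicate block, array weights, robust variances, removal of haemoglobin, mitochondrial and sex-linked transcripts, each sample left out, voom on the recovered reads and protein-coding genes alone, the last of these and voom being added after the data were seen. No pair of libraries agreed within sampling noise, since chi-square per degree of freedom was at least 13.3. Parent genes of pseudogenes were found with blastn 2.17.0 against GENCODE M21 transcripts on GRCm38, in which 11824 of the 12431 tested genes had the same position and symbol. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.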

Results

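RNA was sequenced from 6 mouse hearts at day 4, in a series on how diabetes in pregnancy affects the hearts of offspring. In the control group (n = 3) the mothers had been injected with citric acid while pregnant. In the STZ group (n = 3) they had been injected with streptozotocin, a toxin of the pancreatic beta cell that raises blood glucose. All animals were wild-type ICR mice, an outbred stock. The deposited gene values are normalised for gene length and for a scale the authors set per library. They correspond to between 16707268 and 18082599 whole reads per library. The scale was 1.21 times the recovered reads in control 2 and 0.985 to 1.03 times in the others. Values of control 2 are thus lower than its read total alone would give. Nothing in the labels says whether hearts of a group came from separate litters, so p-values of single genes measure the spread between these 6 samples. Those of camera at the preset correlation compare a list's genes with the other genes tested, and do not measure that spread.

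The series names Meox1, a homeobox transcription factor linked to fibroblast activation, and methylation of lysine 27 on histone H3, so the first question was whether Meox1 and the enzymes that write or erase this mark differed between the groups. Meox1 (ENSMUSG00000001493, GRCm38 chromosome 11, 101877510 to 101894374, minus strand) stood at 13.4 ± 4.79 FPKM in control hearts and 11.6 ± 1.39 FPKM in STZ hearts (SD, n = 3 each). Its log2 fold change, STZ over control, was -0.14 (SE 0.248; limma, BH-adjusted p = 0.930), and the 95% interval ran from -0.73 to 0.44. The control values were 8.64, 18.2 and 13.4 FPKM and the STZ values 11.7, 10.2 and 12.9 FPKM, so the groups overlapped. An exact two-sided permutation test of the 6 Meox1 values gave p = 0.7, where the smallest p that 3 against 3 samples allow is 0.1. Without control 2 the Meox1 difference turned to 0.09, so its direction rested on that library.

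Among the enzymes of the H3K27 mark, Ezh2, the main methyltransferase, stood at 7.40 ± 1.03 FPKM in control and 6.68 ± 0.347 FPKM in STZ hearts (log2 fold change -0.12, SE 0.12). Over fits without 1 library the Ezh2 value ranged from -0.22 (without control 1) to -0.047 (without control 2). The demethylase gene Kdm6b was at 9.61 ± 0.695 FPKM against 11.2 ± 0.517 FPKM, with all 3 STZ values above all 3 control values (log2 fold change 0.20, SE 0.0996; limma, BH-adjusted p = 0.922). Kdm6a, an X-linked demethylase gene that escapes X inactivation, was at 5.88 ± 2.68 and 4.94 ± 0.947 FPKM. Its highest value, 8.95 FPKM, belonged to control 3, the 1 library with Xist reads and no Y-linked reads. Without control 3 the Kdm6a log2 fold change turned from -0.16 to 0.14. Of the 14 tested members of the H3K27 machinery list, 10 had a positive and 4 a negative fold change, with a median of 0.06 (camera, BH-adjusted p = 0.397). The H3K27 list had 7 members on either side and a median of 0.0012 without control 2. None of these members passed the limma threshold, over all genes or adjusted over the list alone.

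**Figure D1:**
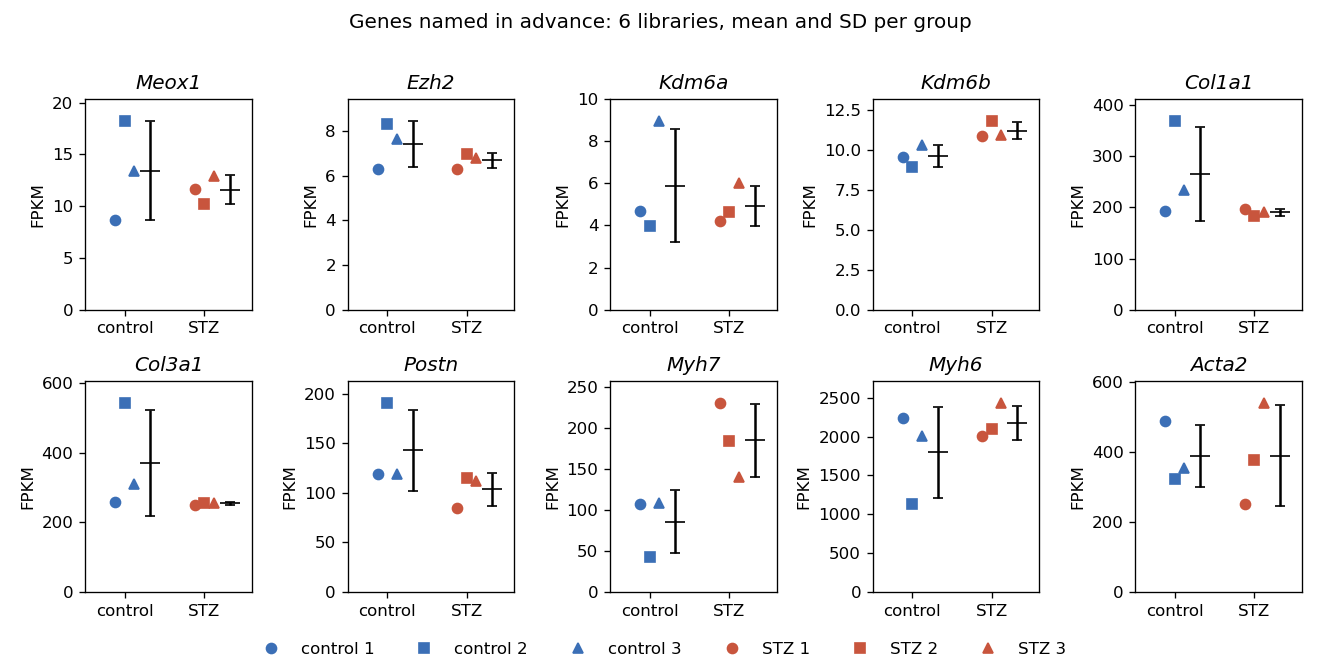
Expression in FPKM (vertical axes, from 0) of 10 genes chosen before the data were examined, with each point 1 library, and the black bar and whiskers the group mean and SD (n = 3). Meox1 overlapped between the groups, at 8.64 to 18.2 FPKM in control and 10.2 to 12.9 FPKM in STZ hearts, while the 3 Myh7 values of STZ hearts, 140 to 230 FPKM, lay above the 3 control values.

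Matrix genes formed the list with the lowest p. Of 24 fibrillar collagen and matrix genes tested, 23 had a lower value in STZ hearts, with a median log2 fold change of -0.45 (camera with a preset correlation, BH-adjusted p = 8.17e-12). The adjusted p was 0.792 with an estimated correlation. Col1a1, which encodes a chain of collagen type I, was at 265 ± 91.4 FPKM in control and 190 ± 7.29 FPKM in STZ hearts (log2 fold change -0.42, SE 0.246). Col3a1 was at 370 ± 151 and 254 ± 3.82 FPKM, and Postn, the matricellular periostin, at 143 ± 41.2 and 104 ± 16.6 FPKM. The proteoglycan genes Lum and Dcn had the lowest p in this list, with log2 fold changes of -0.40 (SE 0.146) and -0.37 (SE 0.139). Fibroblast markers, which share Lum, Dcn and collagen genes with the matrix list, were lower at 10 of 10 members, with a median of -0.41 (camera, BH-adjusted p = 6.71e-07, and adjusted p = 0.792 with an estimated correlation). No single gene of either list passed the limma threshold, also when adjusted over the list alone. Control 2 carried the highest value of Col1a1, 368 FPKM, and of Col3a1, 542 FPKM, and without it the medians were -0.20 for both lists, and the log2 fold change moved from -0.42 to -0.16 for Col1a1, from -0.47 to -0.16 for Col3a1 and from -0.44 to -0.21 for Postn. Both still passed camera there, at BH-adjusted p = 2.00e-08 for matrix genes and 5.10e-05 for fibroblast markers, but not with an estimated correlation, where the adjusted p was 0.839 for each.

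The list for fibroblast activation, which holds Meox1 itself, Postn and Acta2, did not pass. Its 12 tested members had a median of -0.09 (camera, BH-adjusted p = 0.229), and 0.0031 without control 2. Acta2, the smooth muscle actin of myofibroblasts, was at 388 ± 87.9 FPKM in control and 389 ± 144 FPKM in STZ hearts. Tgfb1 was at 7.96 ± 0.29 and 8.17 ± 0.21 FPKM. The TGF-beta and BMP signalling list passed in the lower direction, with 14 of 21 members negative and a median of -0.11 (camera, BH-adjusted p = 0.0214, and adjusted p = 0.792 with an estimated correlation). That call was lost without control 2, at a BH-adjusted camera p of 0.736 and a median of -0.034.

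Among heart muscle genes, Myh7 encodes the slow myosin heavy chain of fetal heart. It was at 85.7 ± 37.8 FPKM in control and 184 ± 45.0 FPKM in STZ hearts, a log2 fold change of 1.19 (SE 0.391; limma, BH-adjusted p = 0.922). Without control 2, whose Myh7 value of 42.1 FPKM was the lowest, the log2 fold change was 0.74. Myh6, the adult isoform, was at 1795 ± 582 and 2177 ± 222 FPKM, and its log2 fold change went from 0.33 to 0.03 without control 2. Nppb, encoding a natriuretic peptide, was at 38.6 ± 29.7 and 59.6 ± 25.9 FPKM, and its log2 fold change of 0.78 was 0.26 without control 1 and 1.36 without control 3. Nppa was at 29.7, 1389 and 20.2 FPKM in the control hearts and at 96.4, 25.3 and 64.1 FPKM in the STZ hearts. Its log2 fold change was -0.81 (SE 1.54) and turned to 1.11 without control 2. The fetal sarcomere list as a whole did not pass, with 6 of 12 members on either side of 0, a median of -0.02 and a mean of -0.32, although camera placed it in the higher direction (BH-adjusted p = 0.758).

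Several cardiomyocyte lists passed in the higher direction. All 15 adult sarcomere genes and all 10 cardiomyocyte markers had positive fold changes, each list with a median of 0.36 (camera, BH-adjusted p = 0.00283 and 0.0137). Calcium handling and ion channel genes (16 of 17 positive, median 0.31) and cardiac transcription factors (15 of 16, median 0.22) passed at camera BH-adjusted p = 0.00493 and 0.0121. Tricarboxylic acid cycle genes (17 of 17, median 0.18) and other histone methylation enzymes (18 of 21, median 0.11) passed at 0.0416 and 0.0182. With an estimated correlation the adjusted p of these lists was 0.792, or 0.879 for the tricarboxylic acid cycle. Control 2 held less of these transcripts than the other control hearts, with cardiomyocyte markers -1.19 log2 units from controls 1 and 3 at the median. Without it none of these lists passed: the median was 0.03 for adult sarcomere genes and 0.02 for cardiomyocyte markers, and for the tricarboxylic acid cycle it turned to -0.08.

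**Figure D2:**
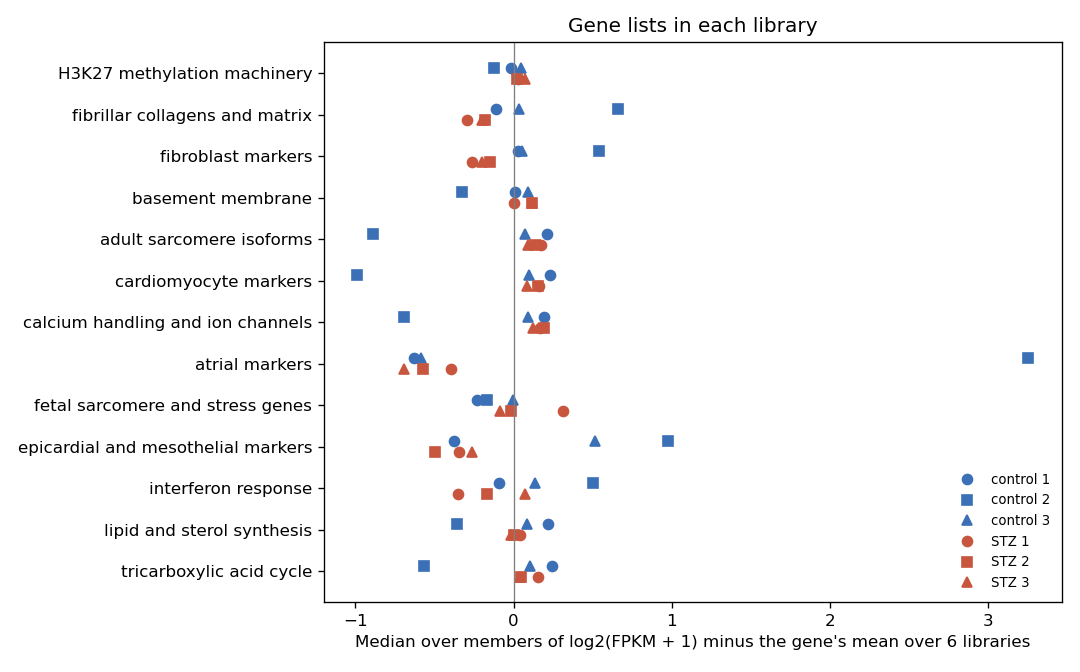
Per-library level of 13 gene lists, as the median over members of log2(FPKM + 1) minus the gene's mean over the 6 libraries (horizontal axis, log2 units), with 1 point per library. Control 2 (blue square) lies apart on most lists, at 3.26 for atrial markers and -0.99 for cardiomyocyte markers, while the 3 STZ libraries lie between -0.29 and -0.18 for fibrillar collagens.

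The remaining lists that passed were all in the lower direction. Atrial markers were lower at 9 of 9 members (median -1.28; camera, BH-adjusted p = 0.000460), and without control 2 the median was 0.0044. Epicardial and mesothelial markers had 7 of 9 members negative with a median of -0.52 (camera BH-adjusted p = 0.000460). Among them were Upk1b, at 4.32 ± 1.92 and 1.67 ± 0.352 FPKM, and Rspo1, at 4.07 ± 2.85 and 1.22 ± 0.208 FPKM. Interferon response genes had 8 of 10 members negative and a median of -0.35 (camera, BH-adjusted p = 0.00107). Isg15, a ubiquitin-like protein gene induced by interferon, was at 5.42 ± 2.83 and 2.11 ± 0.133 FPKM, and Rsad2 at 3.78 ± 1.63 and 1.91 ± 0.824 FPKM. Both lists also passed without control 2, at camera BH-adjusted p = 0.0329 and 0.00715 and medians of -0.19 and -0.22. Even so, the groups overlapped in the median over members of log2(FPKM + 1) minus the gene's mean over the 6 libraries. For the epicardial list this level was -0.37 in control 1 and 0.51 in control 3, against -0.35, -0.49 and -0.27 in STZ 1 to 3. By this level, control 1 lay within the STZ range and only control 3 above it. For the interferon list it was -0.09 and 0.13, against -0.35, -0.17 and 0.07. With an estimated correlation the adjusted p of both lists was 0.792 with all libraries and 0.981 without control 2. With a mean of at least 5 FPKM neither passed (camera BH-adjusted p = 0.0884 for the epicardial and 0.312 for the interferon list), and with array weights the epicardial list did not (0.0679).

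Ribosomal protein genes (20 of 22 negative, median -0.16), unfolded protein and integrated stress response genes (15 of 17, median -0.19) and macrophage markers (9 of 10, median -0.12) passed at camera BH-adjusted p = 0.00107, 0.000547 and 0.0160. Lyz2, encoding lysozyme of macrophages, was at 23.0 ± 6.26 and 13.7 ± 1.39 FPKM, and C1qc at 6.77 ± 4.49 and 4.21 ± 0.487 FPKM. Endocardial and valve markers (6 of 6, median -0.22) and erythroid markers (6 of 8, median -0.89) both passed at camera BH-adjusted p = 0.00517. Cytl1 led the endocardial list, at 8.34 ± 8.40 and 1.603 ± 0.593 FPKM. Control 2 alone was at 17.98 FPKM of Cytl1, and without it the log2 fold change moved from -1.49 to -0.79. It likewise moved from -1.03 to -0.61 for Rspo1, from -0.96 to -0.62 for Isg15, from -0.70 to -0.44 for Rsad2 and from -0.43 to 0.01 for C1qc. With an estimated correlation the adjusted p was 0.792 for each of the atrial, ribosomal, stress response, macrophage, endocardial and erythroid lists. Without control 2 the ribosomal, stress response, macrophage, endocardial, erythroid and atrial lists did not pass, and the macrophage median turned to 0.041, with 7 of 10 members positive. Lyz2 stayed lower there, moving from -0.68 to -0.47, and was the 1 macrophage member past the limma threshold adjusted over the list alone. The medians there were -0.10 for endocardial, -0.27 for erythroid, -0.026 for ribosomal and -0.047 for stress response genes.

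The other 24 lists tested did not pass, with BH-adjusted camera p between 0.05003 and 0.939 and medians between -0.13 and 0.18. In the insulin and IGF list, Igf2r, the receptor that clears IGF2, was at 51.6 ± 7.57 FPKM in control and 70.3 ± 4.73 FPKM in STZ hearts, and Igfbp3 at 21.3 ± 9.39 and 10.3 ± 1.37 FPKM. Among PPAR-responsive genes Ucp3, a mitochondrial uncoupling protein gene, was at 6.96 ± 2.66 and 11.7 ± 3.18 FPKM, and Acot1 at 13.9 ± 5.03 and 19.5 ± 2.04 FPKM. The log2 fold change moved from -0.90 to -0.59 for Igfbp3 and from 0.53 to 0.22 for Acot1 without control 2. Zbtb16, a glucocorticoid-inducible zinc finger gene, was at 0.589 ± 0.11 and 2.16 ± 1.18 FPKM, and the cell cycle inhibitor Cdkn1c at 24.2 ± 2.44 and 19.7 ± 1.49 FPKM. Bckdhb of branched-chain catabolism was at 20.8 ± 2.35 and 16.8 ± 0.439 FPKM. The mitochondrially encoded mt-Co2 was at 799, 328 and 255 FPKM in control hearts and at 176 ± 10.1 FPKM in STZ hearts, and its log2 fold change moved from -1.20 to -0.71 without control 1. None of these genes passed the limma threshold. The mitochondrially encoded list had a median of 0.18 but a mean of -0.05, and camera placed it in the lower direction. Cell cycle genes (18 of 22 positive, median 0.12; camera, BH-adjusted p = 0.135) passed without control 3, at a median of 0.34 and a BH-adjusted camera p of 2.43e-05, but had an adjusted p of 0.550 with an estimated correlation there, and their median was 0.047 without control 2. With all 6 libraries and no filter on low values they also passed, at camera BH-adjusted p = 0.0236.

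Across all 12431 genes tested, 2 passed the limma threshold as higher and 1 as lower in STZ hearts, and all 3 are processed pseudogenes, intronless copies of other genes. They lie outside the rule for named genes and were named after their values were seen. Gm8399 (GRCm38 chromosome 13, 81064684 to 81065800), closest to the gamma-actin gene Actg1, was at 1.05 ± 0.556 FPKM in control and 40.5 ± 2.87 FPKM in STZ hearts (log2 fold change 4.37, SE 0.212; limma, BH-adjusted p = 0.00188). Gm9847 (chromosome 12, 14494561 to 14495159), closest to Socs2, was at 0, 0 and 0.286 FPKM in control hearts and at 5.06 ± 0.742 FPKM in STZ hearts (log2 fold change 2.47, SE 0.158; limma, BH-adjusted p = 0.00545). Gm9847 lost its call without STZ 1, STZ 2 or STZ 3 in turn, at limma BH-adjusted p = 0.0505, 0.0656 and 0.0697. The call on Gm9847 was also lost with a pseudocount of 0.1 (adjusted p = 0.243), with no filter (0.0590) and with voom on recovered reads (0.398). Its log2 fold change ranged from 2.37 (without STZ 1) to 2.59 over fits without 1 library. Over the alternative settings with all 6 libraries it ranged from 2.43 to 5.87. The higher values, such as 5.03 with a pseudocount of 0.1, are on another scale than log2(FPKM + 1). Gm8730 (chromosome 8, 102864845 to 102865798), closest to the ribosomal protein gene Rplp0, was at 51.0 ± 9.95 and 2.83 ± 0.739 FPKM (log2 fold change -3.76, SE 0.194; limma, BH-adjusted p = 0.00188). With the replicate number as a block all 3 lost their calls, Gm8399 and Gm8730 narrowly, at limma BH-adjusted p = 0.0563 and 0.0609. The 3 copies match the parent transcripts at 98.6% (Actg1), 99.5% (Socs2) and 98.7% (Rplp0) of aligned bases, so their values are uncertain. Gm8399 lies within the gene 9330111N05Rik and overlaps an exon of Gm25241, while no annotated gene overlaps Gm8730 or Gm9847. Actg1, Socs2 and Rplp0 themselves had log2 fold changes of -0.01 (SE 0.158), 0.01 (SE 0.126) and 0.04 (SE 0.184).

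At an unadjusted p under 0.05, 145 genes were higher and 177 lower, 322 in total, where a calibrated test with no effect would give 622. Other splits of the libraries into 3 and 3 gave between 291 and 794 such genes, so 322 was within their range. For the real groups the total was 488 without control 2 and 699 without control 3. The 3 values of each group did not overlap at 1061 genes, or 8.54% of those tested, against 10% by chance. Quantile normalization gave 2 genes higher and 2 lower, and with protein-coding genes alone 0 passed in either direction (limma), with 113 higher and 144 lower at an unadjusted p under 0.05. Without control 2 the count was 2 higher and 2 lower, the fourth being Rps2-ps13, another processed pseudogene.

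Because no other named gene passed, the following come from the 5 genes of lowest unadjusted p in each direction under the rule, none past the threshold (limma, BH-adjusted p = 0.922, or 0.298 for mt-Tm). The higher ones were Rapsn, which clusters acetylcholine receptors at the synapse, at 7.22 ± 0.582 and 10.3 ± 0.836 FPKM, and Ttll1, at 5.17 ± 0.762 and 7.48 ± 0.219 FPKM. The kinase gene Syk was at 4.26 ± 0.582 and 6.12 ± 0.426 FPKM, C1qtnf6 at 35.8 ± 6.45 and 52.7 ± 2.27 FPKM, and Syngr2 at 28.9 ± 1.46 and 40.1 ± 4.70 FPKM. The lower ones were the mitochondrial methionine tRNA mt-Tm, at 15.0 ± 3.40 and 5.997 ± 0.276 FPKM, and the acetyl-CoA acetyltransferase gene Acat2, at 9.83 ± 1.95 and 5.42 ± 0.624 FPKM. Lsm5 was at 8.47 ± 2.62 and 2.76 ± 1.35 FPKM, and Vcpkmt at 7.28 ± 0.456 and 5.19 ± 0.556 FPKM. With array weights estimated by limma, mt-Tm passed at a BH-adjusted p of 0.0323. Over the other settings with all 6 libraries its limma BH-adjusted p reached 0.935. The mt-Tm values rested on few reads, 22, 19 and 16 in controls 1 to 3 and 7, 7 and 8 in STZ 1 to 3.

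The control hearts were not alike. Myl7, the atrial myosin light chain, was at 3930 FPKM in control 2 and at no more than 18.3 FPKM in any other library, and Sln, encoding the atrial calcium pump regulator sarcolipin, was at 277.9 FPKM against at most 0.866 FPKM. Across tested genes, Pearson correlations of log2 values lay between 0.922 and 0.929 for pairs with control 2 and between 0.977 and 0.984 for the other 10 pairs. The first principal component took 57.2% of the variance and set control 2 apart from the other 5 libraries. Mitochondrial reads made up 6.84% of control 2 and 12.01% to 14.0% of the others, and haemoglobin reads 1.37% against at most 0.38%. Ribosomal RNA reads made up 0.131% of control 2 against at most 0.0202% elsewhere. The Y-linked gene Ddx3y had between 1360 and 1567 reads in 5 libraries and 0 in control 3, where Xist had 22184 reads against at most 18 elsewhere. The group comparison therefore sets 2 control hearts with Y-linked reads and 1 without against 3 STZ hearts with them.

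**Figure D3:**
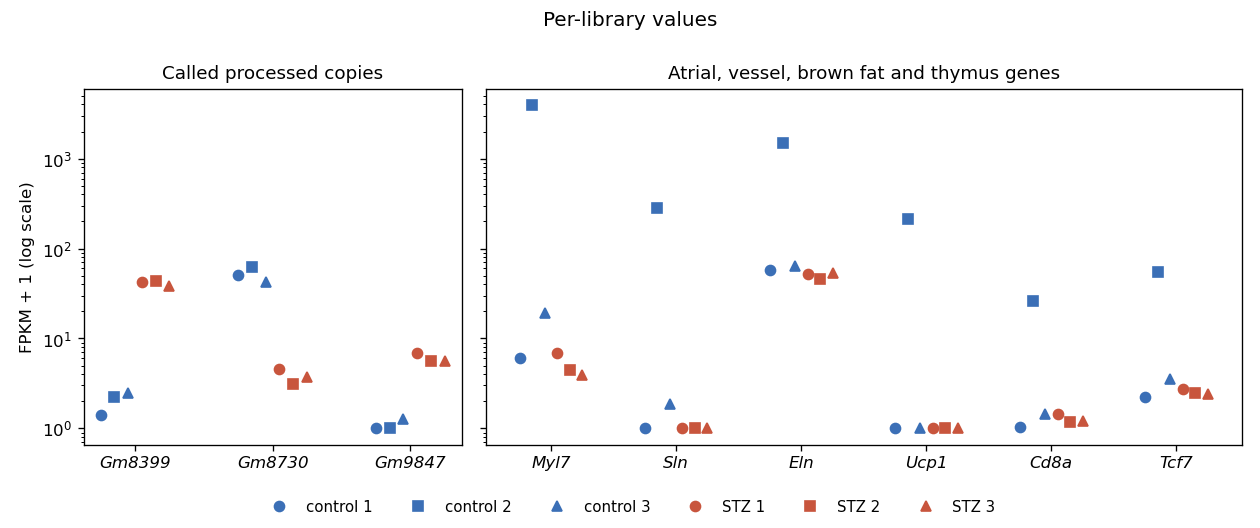
FPKM + 1 on a log axis (vertical) for the 3 called pseudogenes (left) and 6 genes of tissues around the ventricle (right), with 1 point per library. The copies part the 2 groups, as with Gm8399 at 0.425 to 1.48 FPKM in control and 37.3 to 42.6 FPKM in STZ hearts, while the tissue genes part control 2 from the other 5 libraries, as with Myl7 at 3930 FPKM.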

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

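Voom on the recovered reads and the fit on protein-coding genes were chosen after the data were seen, and the other settings before. The planned count tools were not run, because the deposited unit is FPKM, and voom stood in for them. The causes of the changes given here were not tested. Where 2 genes were called higher in STZ hearts, the count was 1 with a pseudocount of 0.1, with no filter, with a mean of at least 5 FPKM and with voom, and 0 with protein-coding genes only, and the gene lost with that pseudocount, no filter or voom was Gm9847. Where 1 gene was called lower, the count was 2 with quantile normalization, 6 with array weights and 0 with protein-coding genes only. At an unadjusted p under 0.05 the counts were 145 higher and 177 lower. Leaving out 1 library at a time gave 1 to 2 genes higher and 1 to 3 lower. The 1 was reached without STZ 2 or STZ 3, and the 3 without control 3. The count of lists past the threshold, 17, was 5 with array weights (4 of the 17, and lipid and sterol synthesis), 0 with an estimated inter-gene correlation and 0 with fry, and leaving out 1 library gave 6 (control 2, with 4 of the 17) to 19 (control 1 or control 3).

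The Meox1 log2 fold change turned to 0.081 with array weights, and ranged from -0.41 (without control 1) to 0.091 (without control 2). Array weights, which gave control 2 a weight of 0.146, also put Nppa at 0.43, the tricarboxylic acid cycle list at -0.073 and the fibroblast activation list at -0.025. With a mean of at least 5 FPKM the lipid and sterol list was at 0.11 and the fetal sarcomere list at -0.062. Tgfb1 was at -0.020 after haemoglobin, mitochondrial and sex-linked transcripts were removed. Over fits without 1 library, Acta2 ranged from -0.31 to 0.24, Nppa from -1.91 to 1.11, C1qc from -0.74 to 0.011 and Kdm6a from -0.35 to 0.14. List medians ranged from -0.15 to 0.10 for lipid and sterol synthesis, -0.18 to 0.36 for mitochondrially encoded transcripts, -0.060 to 0.29 for fetal sarcomere genes, -0.075 to 0.34 for the tricarboxylic acid cycle and -0.16 to 0.0031 for fibroblast activation. In fits with all 6 libraries, 548 comparisons of the other named genes kept direction and side of the threshold, while 6 lost a call, 1 gained one and 2 reversed. Of the list comparisons in those fits, 225 kept both, 20 lost a call, 2 gained one and 4 reversed, by camera's direction and not the median's sign. With array weights the median, but not camera's direction, turned for mitochondrially encoded (-0.080), fetal sarcomere (0.19), macrophage (0.068) and TGF-beta and BMP (0.0065) lists.

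With the replicate number as a block (a paired fit), 0 genes were higher and 0 lower by limma, with 148 and 225 at an unadjusted p under 0.05. The numbers were not treated as pairs: deviations from the group means correlated at 0.02, -0.04 and 0.09 between same-numbered samples, and of the 3 numbers only the third paired best with its own.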

Other observations

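The limma and camera fits and the splits of all 6 libraries were chosen beforehand. The divisions of 5 libraries and the fibroblast marker test were set before their own values were seen. They leave out control 2, however, and bear on lists that already stood out between the groups. The other tests given here were chosen after the results they bear on had been seen. Control 2 held more transcripts of several tissues around the heart than the other 5 libraries. Elastin (Eln), of large arteries, was at 1498 FPKM against at most 63.7 FPKM, and the atrial genes Myl4 and Bmp10 were at 452 and 52.3 FPKM against at most 12.1 and 1.66 FPKM. Ucp1, the uncoupling protein of brown fat, was at 213 FPKM and listed at 0 elsewhere, and the fat hormone gene Adipoq was at 20.4 FPKM and listed at 0 elsewhere. The thymocyte genes Tcf7 and Rag1 were at 53.7 and 25.5 FPKM against at most 2.59 and 0.536 FPKM, and the T cell gene Cd8a was at 24.9 against at most 0.439 FPKM. Skeletal muscle Mylpf reached 13.4 FPKM and liver Ahsg 5.83 FPKM there. Lung markers stayed at or below 2.5 FPKM in every library, and the platelet gene Pf4 was at 19.8 FPKM in control 2 against at most 8.98 FPKM.

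Further genes of the fixed lists, none past the limma threshold, were Myh11 of smooth muscle, at 7.51 ± 2.82 FPKM in control and 4.63 ± 0.423 FPKM in STZ hearts (SD, n = 3), and Nr2f2, a venous and atrial transcription factor gene, at 3.82 ± 0.93 and 2.53 ± 0.366 FPKM. Myh7b was at 7.43 ± 2.45 and 10.9 ± 1.25 FPKM, Cdkn1a at 8.60 ± 1.05 and 10.1 ± 0.363 FPKM, Tef at 13.2 ± 3.56 and 9.53 ± 1.61 FPKM, and Cspg4 of pericytes at 5.43 ± 1.24 and 6.69 ± 0.0798 FPKM. Tmem100 was at 7.77 ± 0.976 and 6.48 ± 0.78 FPKM, Ppm1k at 6.94 ± 2.60 and 8.67 ± 0.823 FPKM, and mt-Co3 at 190.1 ± 61.0 and 144 ± 51.7 FPKM. Without control 2 the log2 fold change moved from 0.53 to 0.28 for Myh7b, -0.55 to -0.29 for Myh11, -0.44 to -0.29 for Nr2f2, 0.28 to 0.12 for Cspg4, -0.41 to -0.26 for Tef, -0.23 to -0.14 for Tmem100, 0.34 to 0.03 for Ppm1k and -0.42 to -0.18 for mt-Co3, which ranged from -0.66 (without STZ 1) to -0.11 (without STZ 3) over fits without 1 library. Without control 2, lipid and sterol synthesis genes were lower in STZ hearts at 14 of 17 members, with a median of -0.15 (camera, BH-adjusted p = 0.000178, and adjusted p = 0.839 with an estimated correlation). Of these, 6 had an unadjusted p under 0.05, among them Insig1 (-0.38), Msmo1 (-0.39), Idi1 (-0.32) and Sqle (-0.31), with no member past the threshold. Of the 10 divisions of these 5 libraries into 2 and 3, 1 (the real one) gave a median as far from 0, and the highest other was 0.12, but 10 divisions are too few for a share under 0.05. The sterol list also stood out under the real division to begin with, so that rank gives no verdict. Mitochondrially encoded transcripts also passed camera there (BH-adjusted p = 0.0329, median -0.18, 12 of 13 members negative), but had an adjusted p of 0.981 with an estimated correlation.

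The first pattern is the distance of control 2 from the other libraries. Fewer reads are argued against, since it held 1.06 times the reads of the smallest other library, and so is blood as the whole cause, since the matrix list was 0.73 log2 units above controls 1 and 3, where blood would dilute it. A candidate explanation is that this sample took in atria, great vessels, thymus and brown fat from around the heart while the others were mostly ventricle. The atrial list was 3.91 log2 units above controls 1 and 3 at its median, and cardiomyocyte markers were -1.19 units from them. Nothing in the labels describes the dissection, and no explanation beyond those named here was tested.

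The second pattern is that the genes called between the groups are processed copies of other genes. Reads shared between near-identical copies may account for part of it. With the called genes left out, 18 of 63 genes at an unadjusted p under 0.01 were processed copies, against 569 of 12428 tested. The odds ratio was 8.57 (Fisher's exact test, p = 2.26e-10, taking genes as independent). Variants shared by littermates could gather on such copies as well, so this excess does not tell read sharing from them. The reads that Gm8399, Gm8730 and Gm9847 gained or lost equal 9.96%, -4.67% and 4.06% of their parents' control reads, too small to see against the parents' standard errors. Whether inherited variants dealt to each animal independently of its group were the whole cause was not decided. An at least 4-fold gap between 3 libraries and the other 3 was found for 3 copies under the real split and for 0 under the 9 others (one-sided binomial p = 0.001, taking copies as independent). Those 3 were the called copies, picked because they part the groups, so that p gives no verdict. Because the calls prompted this count, and this form of the test was kept out of 3 tried, after their values were seen, other gaps were counted with the called copies left out: the p was 0.0128 at a gap of 1 log2 unit (4 copies under the real split, 10 under all), 0.00117 at 0.5 and 0.0826 at 0.25, while a gap of 1.5 left 1 copy, under another split. Beyond the called copies, the real split thus held more than its share by this test at gaps of 1 and 0.5 log2 units. At 0.25 it held 18 of 127 copies, which the test did not tell from that share. Wider gaps left too few copies to say. Other copies, 7 of 572 tested, stood apart at least 4-fold in 1 library alone, 3 of them in control 2. Variants shared by littermates, for which 0 titles number a dam or litter, and an effect of the mothers' treatment cannot be told apart, because the groups differ in dams by design.

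A related case is the ribosomal protein gene Rps2, chosen after its values were seen. Control 2 had 19 reads on Rps2 and 10796 on the copy Rps2-ps13, and control 1 had 4397 and 4497. STZ 1 had 10937 reads on Rps2 and 176 on the copy Rps2-ps10, against 3780 and 2408 in STZ 2. The sum over these 3 genes was between 7873 and 12749 reads in every library.

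The third pattern is the lower matrix and fibroblast lists in STZ hearts. Without control 2 the matrix median was -0.20, with 23 of 24 members negative. That library carried part of the difference, but its tissue content cannot account for the part that stayed without it. Whether that rest is a group difference or spread between the 5 other libraries cannot be told. The list's camera adjusted p there was 0.839 with an estimated correlation. Of the 10 divisions of the 5 other libraries, 1 (the real one) gave a median as far from 0, the highest other being 0.16, and a share under 0.05 is out of reach. The matrix list was taken up for its low p between the groups, so that rank gives no verdict. A lower share of fibroblasts in STZ hearts stays open. Without control 2, fibroblast markers outside the matrix list (Pdgfra, Tcf21, Gsn, Dpt and Pi16) had a median of -0.17. Gsn was at -0.010 and Tcf21 at -0.088, and the median was the value of Dpt, which itself encodes a matrix protein. That median is beyond the limit of -0.1 set beforehand, but the markers belong to the fibroblast list that shows the pattern. For that reason the test was set aside after its value was seen. A direct effect of the mothers' treatment on matrix genes stays open and untested. The matrix list also passed without control 3, the library with Xist reads (camera, BH-adjusted p = 1.35e-08, and adjusted p = 0.782 with an estimated correlation).

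For the counts of calls, the 10 splits of 6 samples into 3 and 3 are too few for a share under 0.05. The real split called 3 genes, and 1 of the 10 splits, itself, called as many, the highest other calling 1. It called 17 lists, and 3 of the 10 splits, itself included, called at least as many, the highest other calling 19 and the lowest 10. Arbitrary splits thus reached the same count of lists, so that count does not set the real groups apart.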
